A study of Danio rerio with 4 samples.

How the data were processed

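Single-cell 3' RNA-seq libraries were made from brain tissue of adult zebrafish, 1 from each of 4 groups: control, fluoxetine, citalopram and sertraline. Per the labels, the tissue was kept cold, dissociated at 37 °C and treated to lyse red blood cells, and libraries were built with the Singleron GEXSCOPE kit and read in paired ends on an Illumina NovaSeq. Doses, exposure times and the number of fish per library are not in the labels. The deposited matrices of each library hold whole-number UMI counts per gene and barcode, and these count values were made by the authors; the aligner, the counting program and the cell caller are not given in the sources used here. The submitters' notes name the mouse and human builds GRCm38 and GRCh38, whereas every gene identifier in the files carries the zebrafish prefix ENSDARG, so the build behind the counts is not known. The files hold 32057 gene identifiers and 28723 gene symbols; 604 symbols have several identifiers, which were summed. No barcode had fewer than 500 UMIs, so the files had been filtered before.

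A barcode was kept as a cell with at least 200 detected genes and at most 20% of its UMIs on mitochondrial genes, and marked doublets were left out. Barcodes under 200 genes numbered 24, 188, 288, 49 in the control, fluoxetine, citalopram and sertraline libraries, those over the mitochondrial limit 20, 26, 44, 21 and doublets 179, 363, 354, 368. Of 70355 barcodes 68431 cells with 161120681 UMIs remained. Doublets were scored per library with the scrublet method of scanpy at an expected doublet share of 6%; its automatic threshold marked very few barcodes, so a fixed score of 0.25 was chosen after this was seen. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 36 clusters over all 4 libraries together. No integration across libraries was done, because library and group are one and the same.

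A cluster was named after a cell type when at least 3 markers of the list were at least 2-fold higher than in the other clusters and detected in at least 10% of its cells, and its 10 leading genes did not favour another list; the named clusters made 19 classes. Of the marker genes 449 matched the files and 15 did not; of the genes in the fixed gene lists 1129 matched and 41 did not. After the clusters were seen, the naming rule was changed so that lists of neuronal subtypes do not count against the general neuron list. Shares of cells have exact binomial 95% intervals. A class share was compared as a ratio only where no more than 30% of the genes that lead its clusters differed over 2-fold between libraries, a rule added after the data were examined. A share is called a large difference at a ratio of 2 or more either way, also set after the shares were seen.

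Within a class, raw UMIs were summed per library and divided by the class total, and the ratio to control received an exact conditional binomial 95% interval, which covers counting error only. A class was compared where both libraries held at least 50 of its cells. Genes were named by a rule fixed beforehand: among genes with at least 50 UMIs in the library with more, ranked by the bound of the interval nearest to 1, the 3 highest and 3 lowest per exposure in granule neurons, other neurons, GABAergic neurons and astroglia, the 3 highest and 3 lowest in all 3 exposures, and 2 on each side for each pair of exposures in granule neurons. Genes with only a clone or locus name, and mitochondrial, ribosomal protein and globin genes, were passed over. A gene with 0 UMIs in 1 library has its ratio given as a bound from a floor of 3 counts. For fixed lists with at least 5 measured members, each with at least 20 UMIs over the 2 libraries, the median log2 ratio with a pseudocount of 1 on the CPM scale was set beside 10000 random lists drawn from 20 expression bins. Up to 4 members per list, those with the most UMIs, could be named. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs. There were no replicates, so no test between groups, p-value or count of changed genes was computed.

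The interval method and the list method were tested on simulated data. In granule neurons with fluoxetine, over 8575 genes, 95.4% of the intervals of unchanged genes covered the true ratio, and 5% of 200 unchanged lists fell outside the central 95% of random lists. The least favourable values were in granule neurons: 8.5% of unchanged lists with citalopram, over 9021 genes, and with sertraline, over 9664 genes, coverage of 88.9% for 45 genes set to a ratio of 4 and 90.9% for 44 genes set to 0.5. Alternatives set before the data were examined changed the gene and mitochondrial limits, doublets, clustering resolution, scaling, pseudocount, minimum counts, random parts of the cells, a split control and the weight of clusters. Lists in cells thinned to 1000 UMIs, and red cells defined as cells with at least 50% globin UMIs, were added later. Leaving out a replicate was not possible. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.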

Results

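Single-cell RNA-seq measured transcripts in brain cells of adult zebrafish in 4 libraries, 1 for each group. The groups were a control and exposures to fluoxetine, citalopram and sertraline, 3 selective serotonin reuptake inhibitors, a class of antidepressant that blocks the serotonin transporter. The series asks how each drug changed brain cells; doses, exposure times and the number of fish behind each library are not given in the labels. The control, fluoxetine, citalopram and sertraline libraries held 13424, 17772, 18632 and 20527 barcodes with 33257078, 34860954, 47611086 and 49746492 UMIs (unique molecular identifiers, 1 per counted transcript molecule). After filtering, 13201, 17195, 17946 and 20089 cells remained, with a median of 1511, 1218, 1464.5 and 1411 UMIs and 748, 668, 752.5 and 720 genes per cell, so cells were shallowest in the fluoxetine library. With 1 library per group there were no replicates and no test between groups: every difference is one between libraries. Ratios are exposure over control, in a gene's part of all UMIs of a cell class, followed in parentheses by an exact 95% interval that covers counting error only. Gene identifiers are those of the files, and chromosomal positions are not given in the sources used here.

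Clusters were named by marker genes, and each name below means cells like that type. Granule neurons of the cerebellum made up 31.1%, 28.9%, 30.1% and 34.7% of the cells in the control, fluoxetine, citalopram and sertraline libraries, and other neurons 22.0%, 19.6%, 19.7% and 18.3%. GABAergic neurons made up 9.76%, 7.27%, 12.3% and 11%, and astroglia or radial glia 7.51%, 9.86%, 6.90% and 6.73%. Red blood cells, the carriers of globin transcripts, were 0.303% of the control cells, 7.75% of the fluoxetine cells, 9.14% of the citalopram cells and 0.473% of the sertraline cells, ratios to control of 25.6 (18.7–36.0), 30.2 (22.1–42.4) and 1.56 (1.07–2.32). Oligodendrocytes, the myelin-forming cells, were 2.11% of control cells and 6.87% and 6.57% of fluoxetine and citalopram cells, ratios of 3.26 (2.86–3.73) and 3.12 (2.74–3.57), while sertraline stood at 2.32% with a ratio of 1.1 (0.950–1.29). Endothelial cells, which line blood vessels, were lower in all 3 exposures, with share ratios of 0.328 (0.261–0.410), 0.410 (0.334–0.503) and 0.716 (0.605–0.848). Immature neurons or neuroblasts had share ratios of 0.711 (0.606–0.834), 0.478 (0.400–0.570) and 0.792 (0.682–0.920), proliferating cells 0.931 (0.728–1.19), 0.482 (0.359–0.645) and 0.948 (0.748–1.2), and oligodendrocyte precursors 0.916 (0.798–1.05), 0.601 (0.516–0.700) and 0.920 (0.806–1.05). Fibroblasts or meningeal cells stood at 0.495 (0.406–0.601), 0.755 (0.635–0.897) and 0.849 (0.722–1.000) of the control share. The share of GABAergic neurons was lower with fluoxetine, 0.744 (0.688–0.805), and higher with citalopram, 1.26 (1.17–1.35), and sertraline, 1.12 (1.05–1.2); that of astroglia was 1.31 (1.21–1.42), 0.919 (0.844–1.000) and 0.896 (0.825–0.973) of control. Purkinje neurons, the output neurons of the cerebellar cortex, numbered 6, 11, 31 and 4 cells and thrombocytes 25, 13, 18 and 61.

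Shares add up to the whole library, so the added red cells of the fluoxetine and citalopram libraries lower the other shares there. Without red and unnamed cells, 49 log2 share ratios stayed within their counting interval and 5 moved beyond it in the same direction. Most share ratios were thus little changed by these cells. Depth may enter as well, which was not tested. Immature neurons had a median of 923 UMIs in the fluoxetine library and 1302 in the citalopram library, against 1401.5 in control. With at least 500 genes per cell, the log2 share ratio of immature neurons moved from -0.49 to -0.087 with fluoxetine and from -1.06 to -0.41 with citalopram. That of fibroblasts with fluoxetine moved from -1.02 to -0.66. The log2 share ratio of red cells moved from 4.68 to 5.79 with fluoxetine and from 0.64 to 1.31 with sertraline. The share ratios of granule neurons, 0.928 (0.890–0.967), 0.966 (0.927–1.01) and 1.12 (1.07–1.16), and of other neurons, 0.894 (0.850–0.940), 0.897 (0.853–0.942) and 0.832 (0.792–0.874), lay near 1. The log2 share ratio of granule neurons with fluoxetine turned direction to 0.12 with at least 500 genes per cell and to 0.089 at clustering resolution 2, and that of other neurons with citalopram to 0.092 with at most 10% mitochondrial UMIs. For 5 classes the genes that define them differed over 2-fold between libraries in more than 30% of cases, so their shares are given without ratios, in the same library order: microglia or macrophages 5.29%, 4.55%, 4.47% and 7.38%, T or NK cells 6.0%, 4.27%, 2.28% and 4.26%, and monoaminergic neurons 1.5%, 0.710%, 0.708% and 1.64%. B cells made up 1.05%, 1.01%, 0.479% and 0.946% and neutrophils 0.0758%, 0.0930%, 0.111% and 0.284%. Clusters that stayed unnamed held 1.85%, 1.24%, 0.652% and 2.08% of cells.

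**Figure D1:**
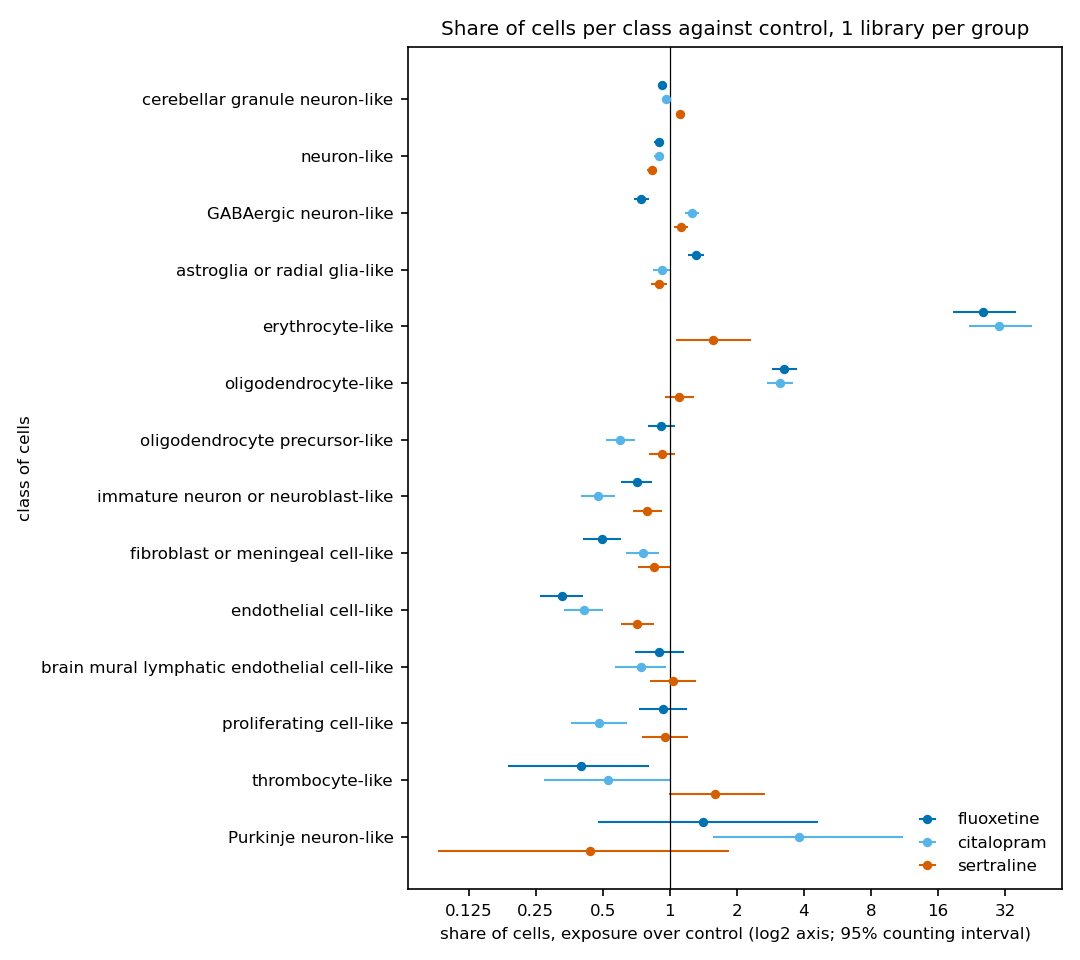
Share of all cells in each class, exposure over control, on a log2 axis, for the 14 classes whose shares were compared; each point is 1 library against the control library and each bar its 95% counting interval. Red cells lie far to the right with fluoxetine and citalopram (25.6 and 30.2 times control) and oligodendrocytes at 3.26 and 3.12 times control, while sertraline lies at 1.56 and 1.1.

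Against control, the 4 main classes of the fluoxetine library had lower transcripts of the heat shock response, of immediate early genes and of part of the circadian clock, and higher transcripts of oxidative phosphorylation. In granule neurons 24 of 28 measured heat shock and chaperone genes were lower, with a median log2 ratio of -0.77. The stress-induced chaperone genes hsp90aa1.2 (ENSDARG00000024746) and hsp70l stood at 0.225 (0.221–0.229) and 0.739 (0.729–0.750) of control, and bag3 (ENSDARG00000039486), a co-chaperone of Hsp70, at 0.111 (0.0974–0.126). Of 37 immediate early genes, which neurons and other cells switch on within minutes of a stimulus, 36 were lower (median -1.08), among them fosab (ENSDARG00000031683) at 0.524 (0.517–0.531), jun at 0.473 (0.466–0.481) and npas4a at 0.341 (0.335–0.348). The circadian clock list had a median of -0.76, with 23 of 33 members lower and 10 higher. The clock repressor gene ciarta (ENSDARG00000058094) stood at 0.0383 (0.0235–0.0593), the clock output gene dbpa (ENSDARG00000063014) at 0.103 (0.0672–0.152) and per1b at 0.151 (0.128–0.177), while rorcb (ENSDARG00000017780), a nuclear receptor of the clock's activating arm, stood at 18.2 (10.5–34.7). Nuclear genes of oxidative phosphorylation were higher in 63 of 67 cases (median 0.48), with the ATP synthase gene atp5f1b at 1.40 (1.34–1.45) and the cytochrome oxidase gene cox4i1 at 1.58 (1.5–1.66). The 13 mitochondrially encoded transcripts had a median of 0.64.

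The other main classes of the fluoxetine library had the same directions for these lists, but not every class did. Over 15 classes, immediate early genes were lower in 10 and higher in 5, among them microglia (median 0.52), B cells (0.43), T or NK cells (0.42) and endothelial cells (0.21), while heat shock genes were lower in all 15. In the remaining neurons the heat shock median was -0.78, the immediate early median -0.55 and the clock median -0.67; in GABAergic neurons they were -0.49, -0.66 and -0.77, and in astroglia -1.02, -1.02 and -0.62. Each of the 12 medians of these 3 lists in the 4 main classes lay below all 10000 random lists of matched expression, which describes these libraries only. The oxidative phosphorylation medians were 0.27, 0.24 and 0.48 in the same order. Astroglia had 28 of 34 apoptosis genes lower (median -0.43), with the survival gene mcl1a at 0.245 (0.235–0.256). They had 36 of 45 lysosome genes higher (median 0.38), with the sphingolipid activator gene psap at 1.45 (1.39–1.51) and the tetraspanin gene cd63 at 1.41 (1.38–1.45). In GABAergic neurons 22 of 33 glutamate receptor and release genes were lower (median -0.24), with grin1a, an NMDA receptor subunit gene, at 0.849 (0.793–0.909). Other neurons held more transcripts of oxt (ENSDARG00000042845), the oxytocin precursor, at 5.61 (5.51–5.71), and fewer of avp (ENSDARG00000058567), the vasopressin precursor, at 0.172 (0.164–0.179). The neuropeptide list had no common direction there, with 24 of 45 genes higher and 21 lower (median 0.033).

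Among single genes with the largest ratios to control, the hormone precursor gene pmchl (ENSDARG00000076978; melanin-concentrating hormone) stood at 20.02 (17.1–23.6) in granule neurons, 16.6 (10.2–29.0) in GABAergic neurons and 19.96 (14.1–29.2) in astroglia. Its 4079 UMIs in granule neurons were spread over 466 cells, with 1570 in a single cell. Free RNA could also give higher values in several classes at once. This was not tested for pmchl in any library, so a change within these classes is not shown. The red-cell gene nt5c2l1 (ENSDARG00000034852) had 115 UMIs in granule neurons against 2, a ratio of 44.6 (12.06–372), beside globin at 0.504% of granule neuron UMIs against 0.0126%. In astroglia ch25hl2 (ENSDARG00000038728), related to cholesterol 25-hydroxylase, stood at 13.5 (10.1–18.4) with UMIs in 88 cells, and the complement factor D gene cfd (ENSDARG00000039579) at 0.0303 (0.0263–0.0347), with 3315 of its 4859 control UMIs in 1 cell. The peptide genes npy (ENSDARG00000036222) and urp2 (ENSDARG00000067781) stood at 0.0345 (0.0232–0.0495) and 0.0430 (0.0312–0.0580) in astroglia. Single control cells held 326 of the 613 npy UMIs and 728 of the 729 urp2 UMIs. The lens crystallin gene crybb2 (ENSDARG00000053512) had 376 UMIs in 8 astroglia against 0 in control, at least 85.4-fold higher. In the remaining neurons, the photoreceptor gene gngt1 (ENSDARG00000035798) and the urotensin gene uts2b (ENSDARG00000017340) were at least 139-fold and 85.4-fold higher, with UMIs in 6 and 2 cells. The gonadotropin-releasing hormone gene gnrh3 (ENSDARG00000056214) stood at 197 (76.6–725), with 621 of 637 UMIs in 1 cell. The calcitonin gene calca (ENSDARG00000056590) stood at 0.00873 (0.00237–0.0225) there, with 424 of 567 control UMIs in 1 cell, and the epithelial S100 gene icn2 (ENSDARG00000055514) was at least 14.8-fold lower. Among peptide genes in GABAergic neurons, pomca (ENSDARG00000043135) stood at 256 (70.32–2117), nppal (ENSDARG00000052948) at 77.5 (32.8–240.2), sst1.2 (ENSDARG00000033161) at 0.00643 (0.00277–0.0127) and rln1 (ENSDARG00000103762) at 0.00441 (0.000111–0.0248), and pyyb (ENSDARG00000035832) was at least 39.9-fold lower. For these 5, single cells held 415, 194, 1288, 273 and 142 of the UMIs in the library with more, and with doublets kept the log2 ratio of nppal was -0.78.

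Granule neurons of the control and sertraline libraries had their largest part in one cluster, led by zgc:122979 and tcima, with 56.2% and 47.1% of them, whereas those of the fluoxetine and citalopram libraries had it in another, led by vsnl1a and cbln12, with 47.2% and 43.0%. With the clusters weighted alike, the granule neuron median of immediate early genes with fluoxetine was -0.75, and with a pseudocount of 10 in place of 1 the clock median of the remaining neurons was -0.35. The median over all genes was itself 0.14 in granule neurons and 0.11 in astroglia with fluoxetine, and 0.10 in granule neurons with citalopram, against -0.0018, -0.0036 and -0.0052 with median-of-ratios scaling. Among the other neurons, the glutamatergic cluster led by slc17a6a was the largest in the control, citalopram and sertraline libraries (36.8%, 50.5% and 40.1%), and another, with 32.4%, in the fluoxetine library.

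**Figure D2:**
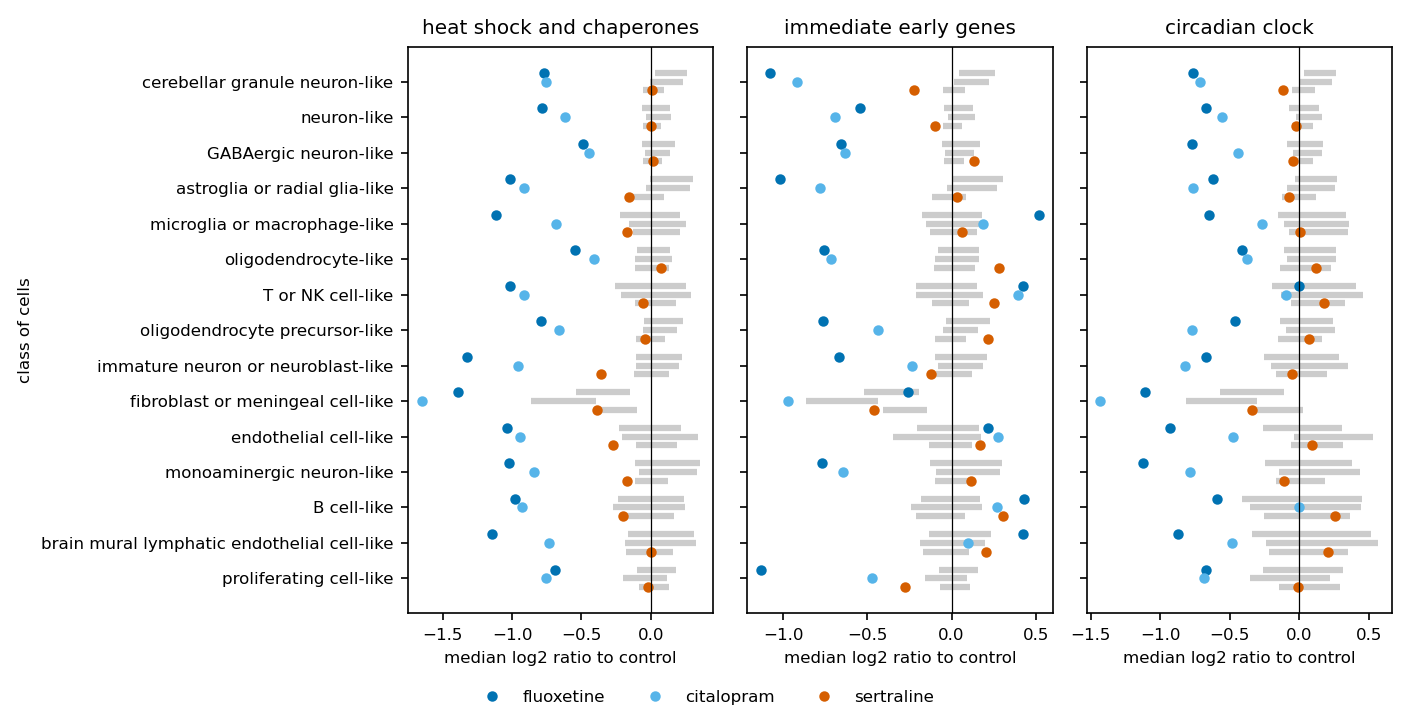
Median log2 ratio to control of heat shock and chaperone, immediate early and circadian clock genes in 15 cell classes; each point is 1 exposure library against the control library and each grey bar the central 95% of 10000 random lists of matched expression. Heat shock medians of fluoxetine and citalopram lie below 0 in all 15 classes, and those of sertraline between -0.39 and 0.075. The lowest values, -1.39, -1.65 and -0.39, are of fibroblasts or meningeal cells, where the median of all genes was itself -0.25, -0.60 and -0.22.

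The main classes of the citalopram library differed from control in the same gene groups as those of the fluoxetine library. In granule neurons 23 of 31 heat shock and chaperone genes were lower (median -0.75), with hsp90aa1.2 at 0.224 (0.221–0.228), hsp70.2 at 0.529 (0.517–0.541) and bag3 at 0.144 (0.129–0.160). All 37 measured immediate early genes were lower (median -0.92), including egr4 at 0.640 (0.633–0.647) and npas4a at 0.467 (0.460–0.475). The clock median was -0.71, with ciarta at 0.0577 (0.0401–0.0808) and the transcription repressor gene bhlhe40 at 0.660 (0.636–0.684), and 65 of 69 oxidative phosphorylation genes were higher (median 0.51), with atp5f1b at 1.49 (1.44–1.55). Heat shock, immediate early and clock medians were -0.62, -0.69 and -0.56 in the remaining neurons, -0.45, -0.63 and -0.44 in GABAergic neurons, and -0.91, -0.78 and -0.77 in astroglia, again each below all 10000 random lists. Over 15 classes, immediate early genes were lower in 10 and higher in 5, such as T or NK cells (0.39) and endothelial cells (0.28).

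Calcium signalling genes were higher with citalopram in 30 of 34 cases in granule neurons (median 0.30, percentile 99.9 among random lists), with the calcium sensor gene vsnl1a at 1.18 (1.14–1.22). In astroglia 22 of 25 glycolysis genes were higher (median 0.40), with the enolase gene eno1b at 1.70 (1.61–1.80) and the lactate dehydrogenase gene ldhba at 1.62 (1.53–1.71). Also in astroglia, 21 of 25 cytokine and inflammatory genes were lower (median -0.53), with the chemokine gene cxcl18b at 0.281 (0.260–0.304). GABAergic neurons had 14 of 19 such genes lower (median -0.53), with the transcription factor gene cebpb at 0.676 (0.576–0.795). This list was lower in 13 of 14 classes with citalopram and in 12 of 14 with fluoxetine. The neuropeptide gene cart3 (ENSDARG00000035852) stood at 11 (10.1–11.9) in the remaining neurons, where 1 cell held 5840 of 7492 UMIs, and pth2 (ENSDARG00000022951), a peptide precursor, at 46.4 (22.3–116) with UMIs in 20 cells.

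Granule neurons of the citalopram library held 1050 oxt UMIs against 121 in control, a ratio of 5.75 (4.76–7.0), with 514 in 1 cell. The gene timd4 (ENSDARG00000077257), a receptor of macrophages for dying cells, stood at 9.47 (4.43–24.2), nt5c2l1 at 43.1 (11.7–359.5) beside globin at 0.429% of granule neuron UMIs, and f13a1a.1 (ENSDARG00000045453), a coagulation factor XIII gene, was at least 38.7-fold lower. Astroglia had more of the interferon-induced gene gbp1 (ENSDARG00000038668), 7.57 (4.8–12.6), although 1 cell held 103 of 271 UMIs, more sc:d217 (ENSDARG00000079645), 19 (6.32–93.6), and more pmchl, 6.65 (4.66–9.80). Lower there were cfd at 0.0103 (0.00830–0.0127), urp2 at 0.0398 (0.0295–0.0528) and the Wnt pathway activator gene rspo1 (ENSDARG00000104340) at 0.0209 (0.00757–0.0466). In the remaining neurons nt5c2l1 stood at 19.6 (10.1–43.5) and calca at 0.0170 (0.00845–0.0307), and icn2 was at least 20.9-fold lower. In GABAergic neurons nppal stood at 31.4 (13.3–97.4), pmchl at 9.71 (5.97–16.9), the calcium-binding protein gene pvalb8 (ENSDARG00000037790) at 12.22 (4.61–45.8), sst1.2 at 0.0392 (0.0320–0.0477) and rln1 at 0.00398 (0.000480–0.0145), and the hypocretin gene hcrt (ENSDARG00000070932) was at least 49.7-fold lower. A single cell held 89 of the 90 pvalb8 UMIs, and in the first random part of the cells its log2 ratio was -0.84. All 81 control UMIs of hcrt in GABAergic neurons were in 1 cell. The low ratios of cfd, urp2, calca, sst1.2 and rln1 rest on the same control cells as with fluoxetine. For each of these genes, 1 control cell held most of the control UMIs. With a pseudocount of 10 the granule neuron heat shock median was -0.47 and the immediate early median of the remaining neurons -0.46, and in cells thinned to 1000 UMIs the latter was -0.41.

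**Figure D3:**
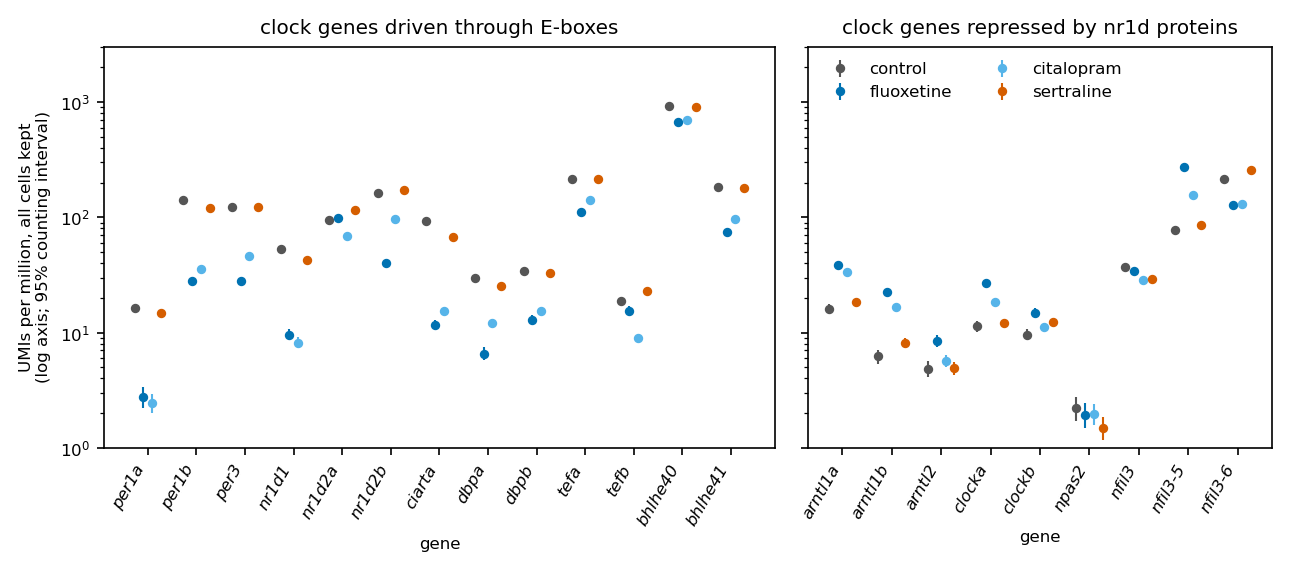
UMIs scaled to the library total (CPM) over all kept cells, on a log axis, of clock genes driven through E-boxes (left) and of clock genes repressed by nr1d proteins (right); each point is 1 library and each bar its 95% counting interval. The fluoxetine and citalopram points of per1a lie at 0.168 and 0.150 of the control level and those of arntl1a at 2.38 and 2.08, while the sertraline points lie at 0.912 and 1.14.

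Over whole libraries, clock genes activated through E-boxes, the binding sites of the CLOCK and ARNTL proteins, were lower with fluoxetine and citalopram, and the clock's activators were higher. The period gene per1a (ENSDARG00000056885) stood at 0.168 (0.134–0.211) with fluoxetine and 0.150 (0.121–0.184) with citalopram, per3 at 0.231 (0.215–0.248) and 0.374 (0.355–0.395), and nr1d1, a repressor of the activators, at 0.18 (0.159–0.202) and 0.153 (0.137–0.171). In the other direction arntl1a (ENSDARG00000006791) stood at 2.38 (2.15–2.64) and 2.08 (1.88–2.30), arntl1b at 3.65 (3.13–4.29) and 2.66 (2.28–3.13), clocka at 2.37 (2.1–2.68) and 1.62 (1.43–1.84), and nfil3-5, whose relatives oppose the clock output genes, at 3.54 (3.39–3.70) and 2.02 (1.93–2.12). Exceptions were nr1d2a, at 1.06 (1.00–1.11) with fluoxetine, and npas2, nfil3 and nfil3-6, at 0.878 (0.618–1.24), 0.913 (0.842–0.991) and 0.598 (0.576–0.621) with fluoxetine and 0.886 (0.643–1.23), 0.765 (0.707–0.827) and 0.607 (0.587–0.629) with citalopram. In the sertraline library per1a stood at 0.912 (0.814–1.02), per3 at 1.01 (0.967–1.05), arntl1a at 1.14 (1.02–1.27) and nfil3-5 at 1.12 (1.07–1.18). The division into these sets was made after their values were seen.

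The main classes of the sertraline library lay closer to control in these groups and differed in sterol genes of astroglia and in inflammatory genes of granule neurons. In granule neurons the heat shock median was 0.0099, with hsp90aa1.2 at 0.949 (0.939–0.959), and the oxidative phosphorylation median -0.038; immediate early genes had a median of -0.22, with 26 of 37 lower, and -0.13 with clusters weighted alike. Over 15 classes, immediate early genes were higher in 10, for example oligodendrocytes (0.28, above all 10000 random lists). Heat shock genes were lower in 11, for example immature neurons (-0.36) and endothelial cells (-0.27), each below all 10000 random lists. Of 28 cytokine and inflammatory genes 24 were higher (median 0.68, above all 10000 random lists), with the chemokine gene ccl35.1 at 1.98 (1.64–2.40) and cebpb at 1.79 (1.52–2.1). The cytokine list was higher in 11 of 15 classes and lower in 4, among them B cells (-0.64, below all 10000 random lists) and T or NK cells (-0.062). The same library had more microglia or macrophages, 7.38% of cells against 5.29%, and il1b at 5.69 (5.36–6.05) over the whole library, so a change made by granule neurons themselves is not shown. Of 40 neuropeptide genes 31 were higher (median 0.70), although the secretory genes cpe and chga, with more UMIs, stood at 0.925 (0.890–0.961) and 0.933 (0.892–0.975), and 36 of 47 lysosome genes were higher (median 0.26), with psap at 1.18 (1.09–1.28). The neuropeptide list was also higher in endothelial cells (1.15), oligodendrocytes (0.80) and T or NK cells (0.58). It was 0.0048 in the remaining neurons and -0.074 in monoaminergic neurons. A change of neuropeptide genes within granule neurons is thus not shown. In astroglia 31 of 35 sterol synthesis and uptake genes were lower (median -0.41, below all 10000 random lists), with the sterol methyl oxidase gene msmo1 (ENSDARG00000055876) at 0.541 (0.50–0.584) and hmgcs1, early in cholesterol synthesis, at 0.713 (0.652–0.780). The list was also lower in some other classes, for example immature neurons (-0.31), monoaminergic neurons (-0.20) and T or NK cells (-0.17). It was higher in B cells (0.13) and endothelial cells (0.14). Also lower in astroglia were 11 of 12 drug-metabolism genes (median -0.41), with cyp1b1 at 0.586 (0.487–0.705), and 20 of 26 astroglial transport genes (median -0.25), with glutamine synthetase, glula, at 0.664 (0.652–0.677). Synaptic vesicle genes were higher in astroglia in 25 of 33 cases (median 0.36), with snap25a, abundant in neurons, at 1.75 (1.62–1.90). This list was also higher in B cells (1.59), T or NK cells (0.87), oligodendrocytes (0.77) and endothelial cells (0.73). In immature neurons it was slightly lower (-0.074). A change within astroglia is thus not shown.

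Single transcription factor genes of the telencephalon, the anterior forebrain, were lower with sertraline; no list of such genes was fixed, so nothing is said of that region as a whole. In astroglia foxg1a (ENSDARG00000070769) had 3 UMIs against 125, a ratio of 0.0167 (0.00341–0.0501), and in the remaining neurons emx3 (ENSDARG00000020417), a pallial transcription factor gene, had 3 against 109, a ratio of 0.0227 (0.00461–0.0682). A differing mix of astroglia is thus not separated from the lower sterol, drug-metabolism and transport genes of astroglia with sertraline. Over whole libraries, with genes chosen after their values were seen, foxg1a stood at 0.389 (0.332–0.456), 0.715 (0.635–0.806) and 0.0792 (0.0603–0.103) with fluoxetine, citalopram and sertraline and tbr1b at 0.477 (0.397–0.571), 0.844 (0.734–0.971) and 0.288 (0.238–0.348). The midbrain and hindbrain gene en2a stood at 0.914 (0.861–0.971), 0.962 (0.910–1.02) and 1.19 (1.13–1.26). The hypothalamic peptide gene npvf (ENSDARG00000036227) had 0 UMIs in the control and citalopram libraries, 35 with fluoxetine and 4223 with sertraline. In sertraline it was at least 854-fold higher in the remaining neurons, with UMIs in 82 cells, and at least 95.5-fold and 33.3-fold higher in granule and GABAergic neurons. Free RNA could also give the values in granule and GABAergic neurons, which was not tested.

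Other large differences with sertraline were of genes held by few cells or by several classes at once. Granule neurons had 232 UMIs of the enamelin gene enam (ENSDARG00000092730) in 17 cells, at least 42.0-fold higher than control, and astroglia 173 in 4 cells (92 in 1), at least 40.2-fold higher. The related mineral-binding protein gene scpp7 (ENSDARG00000074132) was at least 27.0-fold higher in astroglia. The granulin gene grn2 (ENSDARG00000088641) stood at 75.9 (13.4–3018) in GABAergic neurons and was at least 21.4-fold higher in astroglia. The gene c16h2orf66 (ENSDARG00000116758) stood at 62.6 (21.2–305) in granule and 18.7 (7.83–58.2) in GABAergic neurons. In the remaining neurons pth2 stood at 138 (66.7–344) with 799 of 1170 UMIs in 1 of 32 cells, hcrt at 193 (34.3–7659) with 192 of 234 UMIs in 1 cell, and dbx1a (ENSDARG00000086393), a homeobox gene, at 0.0129 (0.000321–0.0745), with 44 of 64 control UMIs in 1 cell. In granule neurons pmchl, avp and f13a1a.1 stood at 0.134 (0.0919–0.191), 0.239 (0.167–0.339) and 0.0635 (0.0280–0.127). In GABAergic neurons rln1, hcrt and pyyb stood at 0.0123 (0.00449–0.0272), 0.0208 (0.00420–0.0630) and 0.0429 (0.0210–0.0791), each with most control UMIs in 1 cell, where the log2 ratio of pyyb was 0.76 with doublets kept and 2.57 in the first random part of the cells. In astroglia the glutathione transferase gene gsta.2 (ENSDARG00000039832) and fam167aa (ENSDARG00000067665) stood at 0.0182 (0.00370–0.0546) and 0.0547 (0.0144–0.149).

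In all 3 exposures, transcripts of myelin were higher in cells named granule neurons and in most other classes. Here and in the next paragraph, the 3 ratios of a gene share the same control library. An unusual value there would move all 3 the same way. In granule neurons their list had medians of 0.73, 0.83 and 0.52 with fluoxetine, citalopram and sertraline, each above all 10000 random lists. The list was higher in 15, 15 and 12 of 15 classes, with fluoxetine for example in B cells (2.76), proliferating cells (1.63) and endothelial cells (1.5), but in oligodendrocytes themselves it stood at 0.036, 0.042 and -0.12. Higher values in cells that make no myelin are what free RNA of oligodendrocytes would give, so a change within granule neurons is not shown. The myelin basic protein gene mbpa (ENSDARG00000036186) stood at 4.74 (4.04–5.60), 4.64 (3.96–5.46) and 2.96 (2.52–3.49), beside the larger oligodendrocyte shares of the first 2 libraries. With sertraline that share was 1.1 (0.950–1.29) of control, so its mbpa value had no clearly larger oligodendrocyte share beside it. Also higher in granule neurons in all 3 were cd59 (ENSDARG00000090615), an inhibitor of complement, at 3.14 (2.84–3.47), 3.98 (3.61–4.39) and 2.16 (1.95–2.39), and the immunoglobulin gene ighv1-4 (ENSDARG00000096301 and ENSDARG00000096355, 2 identifiers summed) at 5.17 (2.55–11.85), 4.42 (2.18–10.1) and 8.99 (4.61–20.04). Free RNA of other cells was not tested for cd59 or ighv1-4, so a change within granule neurons is not shown for either. Lower in all 3 were f13a1a.1, ciarta and the calcium pump gene atp2a1 (ENSDARG00000020574), the last at 0.199 (0.162–0.242), 0.299 (0.254–0.351) and 0.566 (0.499–0.642). In astroglia aldh1a2 (ENSDARG00000053493), which makes retinoic acid, stood at 2.2 (1.95–2.5), 1.85 (1.64–2.1) and 2.11 (1.87–2.40). There the transcription factor gene pou3f2a (ENSDARG00000070220) at 3.15 (2.5–4.02), 2.51 (1.99–3.20) and 1.93 (1.5–2.49), and the polyamine enzyme gene sat1b (ENSDARG00000032272) at 2.89 (2.12–4.02), 2.31 (1.69–3.22) and 2.07 (1.49–2.91). Lower in astroglia were npy and cfd, in each of which 1 control cell held most control UMIs, and crabp2a (ENSDARG00000073978), a retinoic acid-binding protein gene, the last at 0.0841 (0.0485–0.138), 0.111 (0.0718–0.166) and 0.263 (0.189–0.361). In the second random part of the astroglia the log2 ratio of aldh1a2 with sertraline was -0.19.

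In the remaining neurons cdaa (ENSDARG00000111188), a cytidine deaminase gene, stood at 8.97 (4.26–21.8), 7.57 (3.64–18.2) and 7.22 (3.47–17.4), pth2 with fluoxetine at 11.7 (5.36–30.1) (34 of 66 UMIs in 1 cell), and the cofilin gene cfl1l (ENSDARG00000012972) at 0.153 (0.0737–0.287), 0.158 (0.0865–0.271) and 0.148 (0.0813–0.254). There f13a1a.1 stood at 0.0556 (0.0148–0.147), 0.0197 (0.00235–0.0734) and 0.0371 (0.00989–0.0983), and prlh (ENSDARG00000099462), of which 1 control cell held 185 of 186 UMIs, was at least 50.1-fold and 70.6-fold lower with fluoxetine and citalopram and stood at 0.0177 (0.00479–0.0462) with sertraline. In GABAergic neurons the axon guidance gene ntn1b (ENSDARG00000022531) stood at 8.30 (4.25–18.1), 5.92 (3.10–12.7) and 3.99 (2.05–8.68), and the glycine transporter gene slc6a5 (ENSDARG00000067964) at 15.6 (5.75–59.5), 5.16 (1.86–19.9) and 10.7 (4.00–40.2). Single cells held 25 of 52, 13 of 38 and 41 of 76 slc6a5 UMIs. A single cell held 50% or more of the UMIs in the library with more of them for 0 of 21 named genes in granule neurons, 8 of 17 in the remaining neurons, 9 of 14 in GABAergic neurons and 4 of 19 in astroglia.

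Set against each other in granule neurons, fluoxetine and citalopram lay closer together than either lay to sertraline. Over 6672 genes the SD of the log2 ratio beyond counting error was 0.203 between fluoxetine and citalopram, 0.347 between fluoxetine and sertraline and 0.341 between citalopram and sertraline, against 0.349, 0.350 and 0.197 between control and fluoxetine, citalopram and sertraline. The covariance of log2 ratios to control was 0.118 for fluoxetine and citalopram, 0.0362 for fluoxetine and sertraline and 0.0387 for citalopram and sertraline, where unchanged groups simulated against the shared control gave 0.0217, 0.0216 and 0.0216 over 100 draws. The correlation across genes was 0.788 for fluoxetine and citalopram against 0.556 simulated. It lay below the simulated value for fluoxetine and sertraline, 0.371 against 0.584, and for citalopram and sertraline, 0.397 against 0.596. The simulated unchanged groups lacked the spread beyond counting error given above, and such spread lowers a correlation. The lower correlations thus do not show these pairs to be less alike than unchanged groups, and their covariances lay above the simulated ones. Genes are not independent replicates. With each exposure set against its own part of the control cells the covariances were 0.0953, 0.0145 and 0.0178, which still share the control library, and with at least 200 UMIs the fluoxetine and sertraline covariance was 0.0225. The glucocorticoid-responsive gene fkbp5 (ENSDARG00000028396), a partner of the glucocorticoid receptor, stood at 13.4 (10.4–17.5) in fluoxetine over citalopram and 0.0687 (0.0526–0.0882) in citalopram over sertraline, having been 2.67 (2.29–3.12), 0.199 (0.149–0.264) and 2.91 (2.51–3.38) of control. The ceruloplasmin gene cp (ENSDARG00000010312) and ifi45 (ENSDARG00000017489), of the interferon list, stood at 0.230 (0.144–0.356) and 0.192 (0.0915–0.366) in fluoxetine over citalopram. The gene pmchl stood at 11.6 (10.4–12.8) in fluoxetine over citalopram, 149 (109–210.4) in fluoxetine over sertraline and 12.9 (9.30–18.4) in citalopram over sertraline, and nt5c2l1 at 41.1 (15.6–153) and 39.7 (15.1–148) in the last 2. Sertraline had 232 enam and 128 scpp7 UMIs in granule neurons, where fluoxetine had 1 and 0 and citalopram none of either, and 528 npvf UMIs against 0 in citalopram. Doses and times are not in the labels, so matched exposure cannot be assumed.

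For the genes of serotonin itself, tph1a (a tryptophan hydroxylase gene, whose product starts serotonin synthesis) was lower over the whole fluoxetine and citalopram libraries, at 0.161 (0.130–0.198) and 0.243 (0.207–0.283), and stood at 1.07 (0.968–1.18) with sertraline. The tyrosine hydroxylase gene th2 (dopamine synthesis) stood at 0.324 (0.275–0.381), 0.363 (0.316–0.418) and 1.61 (1.46–1.77). The serotonin transporter gene slc6a4a (ENSDARG00000061165), the product of which these drugs block, had 78, 20, 49 and 43 UMIs in the control, fluoxetine, citalopram and sertraline libraries, ratios of 0.249 (0.144–0.412), 0.445 (0.305–0.645) and 0.371 (0.249–0.545). Of the 78 control UMIs, 66 were in a few GABAergic neurons, described below, so these ratios rest largely on those cells. The paralogue of slc6a4a, slc6a4b, stood at 0.878 (0.508–1.51), 0.915 (0.558–1.51) and 2.19 (1.45–3.39). The neuronal tryptophan hydroxylase gene tph2 (ENSDARG00000057239) had 158, 109, 281 and 220 UMIs, ratios of 0.671 (0.521–0.862), 1.26 (1.03–1.54) and 0.936 (0.760–1.16). Within monoaminergic neurons, tph1a relative to all UMIs stood at 0.275 (0.208–0.359), 0.447 (0.373–0.534) and 0.833 (0.745–0.931) of control. Cells of this class made up 1.5%, 0.710%, 0.708% and 1.64% of the control, fluoxetine, citalopram and sertraline libraries. Fewer such cells may thus also enter the lower whole-library values. The share of these cells with a tph1a UMI, each thinned to 1000 UMIs, was 39.1% (31.7–46.8), 25.9% (15.3–39.0), 37.1% (27.5–47.5), 38.4% (32.8–44.2) in the control, fluoxetine, citalopram and sertraline libraries, with overlapping intervals. Thinning left 169, 58, 97 and 297 cells and removed 29, 64, 30 and 32. The unthinned shares were 44.4%, 24.6%, 37.0% and 40.7% and the median depths 1584.5, 993.5, 1464 and 1703 UMIs. The share in oligodendrocytes, which should lack the gene, was 0.398% in control and 0% in the others at median depths of 2476.5, 1744.5, 2373 and 2281 UMIs.

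Few cells carried tph2, and they fell into different classes by library. In the remaining neurons tph2 had 3, 80, 66 and 114 UMIs, so that its ratios of 33.0 (10.9–163), 19.3 (6.33–96.1) and 31.4 (10.5–154) were among the highest shared ones, whereas GABAergic neurons had 135, 9, 189 and 46. Cells with at least 3 tph2 UMIs numbered 0, 6, 3 and 7 in the former and 3, 1, 6 and 4 in the latter, and with doublets kept the log2 ratio of tph2 in the former was -0.52 with citalopram. The transporter gene slc6a4a, at 0.0547 (0.0110–0.167), 0.189 (0.112–0.308) and 0.136 (0.0736–0.238) in GABAergic neurons, rested on 3 control cells, of which 1 held 33 of 66 UMIs. In the remaining neurons slc6a4a went the other way, with 5, 15, 19 and 11 UMIs in the control, fluoxetine, citalopram and sertraline libraries. Of 10 serotonin synthesis, transport and breakdown genes measured in GABAergic neurons with sertraline, 8 were lower (median -0.67), among them ddc, which completes serotonin synthesis, at 0.534 (0.385–0.740). With sertraline the same list had medians of 0.58 in granule neurons, -0.061 in the remaining neurons, -0.35 in astroglia and 0.18 in monoaminergic neurons, so it had no common direction. With fluoxetine and citalopram it stood at 0.23 and -0.24 in the remaining neurons and -0.15 and 0.21 in monoaminergic neurons. Serotonin receptor genes in the remaining neurons had medians of -0.28, -0.13 and 0.14 with fluoxetine, citalopram and sertraline, with htr1ab at 0.540 (0.450–0.645), 0.575 (0.491–0.672) and 1.07 (0.942–1.22).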

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

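Barcodes with under 200 genes, which no comparison uses, drew attention because they made up more of the fluoxetine library (1.058%, interval 0.913 to 1.22) and of the citalopram library (1.546%, 1.37 to 1.73) than of the control library (0.179%, 0.115 to 0.266). They numbered 24, 188, 288 and 49 in the control, fluoxetine, citalopram and sertraline libraries, and globin genes held 12.3%, 71.4%, 49.1% and 6.94% of their UMIs. Red cells carry few kinds of transcript, so these barcodes go with the larger share of red cells in the same 2 libraries. The difference was not tested between groups, since each group is 1 library.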

How the results depend on the processing

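Of the values recomputed under other settings, those with cells thinned to 1000 UMIs in gene lists, and red cells defined by at least 50% globin UMIs, were chosen only after the result was seen; the others were set before the data were examined. Values below are log2 ratios, medians of log2 ratios or covariances, with the reported value in parentheses, and the cause of each shift was not tested. Among log2 share ratios 393 stayed within their counting interval, 51 moved beyond it in the same direction and 3 turned direction. For single genes the counts were 936, 166 and 7, for list medians 977, 151 and 16, for covariances 10, 13 and 1, and for shares of cells with a UMI 14 and 10, with none reversed. In the 5 classes whose shares were not compared, 25 of 120 alternatives moved and 0 reversed.

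For shares with at least 500 genes per cell the values were: granule neurons with fluoxetine 0.12 (-0.11), red cells with fluoxetine 5.79 (4.68), red cells with sertraline 1.31 (0.64), immature neurons with fluoxetine -0.087 (-0.49), immature neurons with citalopram -0.41 (-1.06) and fibroblasts with fluoxetine -0.66 (-1.02). Clustering resolution 2 gave granule neurons with fluoxetine 0.089 (-0.11), and a limit of 10% mitochondrial UMIs gave other neurons with citalopram 0.092 (-0.16).

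With doublets kept, the values were tph2 in other neurons with citalopram -0.52 (4.27), nppal in GABAergic neurons with fluoxetine -0.78 (6.28), pyyb in GABAergic neurons with sertraline 0.76 (-4.54), immediate early in other neurons fluoxetine -0.43 (-0.55), GABAergic neurons sertraline 0.21 (0.14) and neuropeptides in GABAergic neurons citalopram 0.27 (-0.11). The first random part of the cells gave pvalb8 in GABAergic neurons with citalopram -0.84 (3.61), pyyb in GABAergic neurons with sertraline 2.57 (-4.54) and nppal in GABAergic neurons with sertraline -0.75 (2.2), and the second gave aldh1a2 in astroglia with sertraline -0.19 (1.08).

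For lists with members of at least 100 UMIs, the values were glutamate receptors in granule neurons fluoxetine 0.012 (-0.044), neurotrophins in granule neurons fluoxetine 0.0070 (-0.058), clock in granule neurons citalopram -0.995 (-0.71), sterol synthesis in other neurons sertraline 0.014 (-0.087) and apoptosis in GABAergic neurons citalopram 0.0087 (-0.13). Members with at least 1 UMI gave serotonin synthesis in other neurons citalopram 0.073 (-0.24), complement in GABAergic neurons citalopram 0.071 (-0.22) and serotonin receptors in astroglia citalopram -0.092 (0.47). A pseudocount of 10 gave heat shock in granule neurons citalopram -0.47 (-0.75), astroglia fluoxetine -0.83 (-1.02), immediate early in other neurons fluoxetine -0.38 (-0.55), other neurons citalopram -0.46 (-0.69) and clock in other neurons fluoxetine -0.35 (-0.67), other neurons citalopram -0.42 (-0.56), GABAergic neurons fluoxetine -0.63 (-0.77), astroglia citalopram -0.58 (-0.77). With median-of-ratios scaling the values were immediate early in granule neurons fluoxetine -1.21 (-1.08), heat shock in granule neurons fluoxetine -0.90 (-0.77) and clock in granule neurons fluoxetine -0.90 (-0.76). With clusters weighted alike they were immediate early in granule neurons fluoxetine -0.75 (-1.08), granule neurons citalopram -0.66 (-0.92), granule neurons sertraline -0.13 (-0.22), heat shock in granule neurons fluoxetine -0.64 (-0.77), clock in other neurons fluoxetine -0.54 (-0.67), other neurons citalopram -0.67 (-0.56) and GABA and glycine receptors in GABAergic neurons sertraline 0.046 (-0.086). In cells thinned to 1000 UMIs they were immediate early in granule neurons fluoxetine -1.26 (-1.08), other neurons citalopram -0.41 (-0.69), other neurons sertraline -0.0049 (-0.097), GABAergic neurons fluoxetine -0.53 (-0.66), GABAergic neurons sertraline 0.20 (0.14), neuropeptides in granule neurons fluoxetine 0.078 (-0.12), astroglia citalopram 0.36 (-0.24), cytokines in granule neurons fluoxetine 0.0015 (-0.12), clock in granule neurons fluoxetine -0.88 (-0.76), granule neurons citalopram -0.93 (-0.71), astroglia fluoxetine -0.44 (-0.62), astroglia citalopram -0.52 (-0.77), apoptosis in GABAergic neurons citalopram 0.022 (-0.13), unfolded protein response in GABAergic neurons citalopram 0.040 (-0.094), heat shock in GABAergic neurons sertraline 0.086 (0.019) and complement in GABAergic neurons sertraline -0.032 (0.26), astroglia sertraline -0.021 (0.22).

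With the control cells split between the exposures, the values were granule neuron covariance of fluoxetine and sertraline 0.0145 (0.0362), granule neuron covariance of citalopram and sertraline 0.0178 (0.0387) and astroglia covariance of fluoxetine and sertraline -0.00437 (0.0284). Genes with at least 200 UMIs gave granule neuron covariance of fluoxetine and sertraline 0.0225 (0.0362). No paired analysis was possible because each group is 1 library and the labels pair no animals across groups. Leaving out a replicate was not possible either, as there were no replicates.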

Other observations

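Several genes of inflammation and of myeloid cells were higher with sertraline than in control over the whole libraries; they were chosen after their values were seen, and no list of them was fixed. That library also held more microglia or macrophages (7.38% against 5.29%) and neutrophils (0.284% against 0.0758%), so these ratios do not show activation of such cells. The matrix metalloproteinase genes mmp13a and mmp9, which remodel tissue in inflammation, stood at 5.61 (5.32–5.92) and 3.84 (3.51–4.2), the interleukin gene il1b at 5.69 (5.36–6.05) and the chemokine genes cxcl8a and ccl34a.4 at 3.12 (2.90–3.36) and 10.1 (9.51–10.8). The granulin genes grn1 and grn2 stood at 4.1 (4.01–4.19) and 120.1 (102–142), and the neutrophil genes mpx and lect2l at 4.61 (3.60–5.99) and 6.30 (5.64–7.07), where fluoxetine had 2.09 (1.57–2.81) and 3.92 (3.48–4.42) and citalopram 3.00 (2.32–3.94) and 3.15 (2.80–3.55). The lysozyme gene lyz stood at 26.2 (19.7–35.6), 20.8 (15.6–28.2) and 12.4 (9.32–16.9) with fluoxetine, citalopram and sertraline. A cluster of 52 microglia or macrophages led by grn2 and ccl34a.4 held sertraline cells and none of the other libraries, so it is as much that library as a cell type.

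In microglia or macrophages with sertraline, 21 of 25 glycolysis genes were higher (median 0.74), with gapdhs at 1.64 (1.58–1.70), as were 66 of 69 oxidative phosphorylation genes (median 0.72). The cells behind this class differed between libraries: one cluster held 35.9% of them with sertraline against 17.3% in control, and 2 others 22.6% and 38.0% against 33.1% and 49.6%, so a shift between kinds of microglia is not separated from a change within them. All 31 measured synaptic vesicle genes were higher too (median 0.92), with snap25a, abundant in neurons, at 2.12 (1.95–2.30). As given above, the synaptic vesicle list was also higher in several other classes with sertraline, so a change within microglia is not shown. Complement and antigen presentation genes were lower in 16 of 24 cases (median -0.28), with cd74a at 0.705 (0.698–0.712), and higher with fluoxetine and citalopram (medians 0.35 and 0.34). Interferon genes had medians of 0.35, 0.73 and -0.15 with fluoxetine, citalopram and sertraline, with irf1b at 2.23 (2.01–2.47), 1.29 (1.16–1.43) and 0.446 (0.398–0.50). The microglial fosab ratio was 3.28 (3.20–3.37) with fluoxetine and 2.69 (2.62–2.76) with citalopram, opposite in direction to that of granule neurons.

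Of the tests of 3 patterns that follow, those of the clock genes, of red-cell genes without nt5c2l1 and of the heat shock value set against neuronal activity were chosen only after the result was seen; the others were set down before. The count of higher clock genes replaced an earlier test on a set divided off after its values were seen. A pattern of neutrophil genes in sertraline had also been set down for weighing and was given up for the clock pattern once the clock values were seen, so its tests were not run.

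Globin transcripts and red cells were higher with fluoxetine and citalopram than in control. Other red-cell genes (alas2, slc4a1a, hemgn and nt5c2l1) were also higher in granule neurons. In the library nearer control they stood at 3.712 times control, with a lower interval bound of 2.69. This passed the bound set against globin made by neurons, but red-cell RNA in these cells does not exclude some globin of their own. Much of the value of 3.712 came from nt5c2l1, without which the other 3 genes stood at 3.08 (2.2–4.41) and 1.88 (1.32–2.73) in granule neurons with fluoxetine and citalopram, but at 4.44 (3.40–5.87) and 4.13 (3.19–5.41) in the remaining neurons. Without nt5c2l1 the granule neuron value with citalopram fell short of that bound. The ratio of hbaa1 to hbba1 in granule neurons lay within 1.227 times that of red cells in both libraries, as free RNA from red cells could give. Left open is why red cells were more numerous in these 2 libraries, whether by the exposure or by the preparation, since each group is 1 library and an effect of the exposure on blood was not tested.

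Heat shock genes in all 15 classes, and immediate early genes in 10 of 15, were lower with fluoxetine and citalopram than in control. With granule neurons thinned to 1000 UMIs the immediate early median was still -0.9158 in the library nearer 0, past the bound set against depth. It covered the 1066, 1173 and 1789 cells deep enough of 4109, 4965 and 5396 in control, fluoxetine and citalopram. Random thinning leaves a gene's expected part of a cell's UMIs as it was, so this value cannot decide on depth. The same thinning moved this median from -1.08 to -1.26 in granule neurons with fluoxetine. In the remaining neurons with citalopram it moved from -0.69 to -0.41. The tables argue against changed neuronal activity as the whole cause of the heat shock part. Heat shock genes had a median of -0.9165 over 5 non-neural classes in the library nearer 0. For immediate early genes, the value set down beforehand was the median over the same 5 classes. At 0.21 and 0.19 with fluoxetine and citalopram, it met the bound for neuronal activity. These classes go both ways, from oligodendrocytes at -0.76 and -0.71 to microglia at 0.52 with fluoxetine. Neuronal activity is thus neither shown nor excluded for the immediate early genes. A difference in handling may account for the heat shock part, the median of which lay under -0.3 in 100% of 15 classes, while the exposure itself is untested against it, as library, exposure and preparation cannot be told apart with 1 library per group.

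Clock genes split the libraries in the same way. Genes repressed by the nr1d proteins had a median of 0.76 over 11 classes with fluoxetine and 0.47 over 12 with citalopram. The E-box-driven genes had -1.52 and -0.99 over 15 classes. With sertraline the medians were 0.21 over 13 classes and 0.00220 over 15. Some classes held only 3 or 4 members of the repressed set, under the minimum of 5 used for lists. With citalopram its values ranged from -0.77 to 1.79. Of the whole clock list, fixed before the data, some members were over 1.5-fold higher in both the fluoxetine and citalopram libraries. They numbered 6, 3, 5 and 5 in granule neurons, the remaining neurons, GABAergic neurons and astroglia. Each count lay at a percentile of 98.77 or higher among random lists, past the bound set against lower stress-induced transcription as the whole cause. That explanation is not excluded, since a fall of nr1d1, a repressor of the activators, could itself raise such genes. Tissue taken at another time of day may underlie the pattern. Yet both sets moved apart past the chosen limits in 58.33% of 12 classes in the weaker library, citalopram, short of the 80% that had been set. Sampling times are not in the labels, and a change of the clock by the exposure is untested.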
